A study of Mus musculus with 16 samples.

How the data were processed

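Gene expression was measured in the hippocampus of mice from 2 transgenic lines on 16 Affymetrix Mouse Genome 430 2.0 arrays, which hold 45101 probe sets. VP16-CREB joins the transcription factor CREB to the activation domain of the viral protein VP16, so that it activates transcription without the usual upstream signal, and in these mice it is expressed when doxycycline (dox) is withdrawn. A-CREB is a dominant negative inhibitor that pairs with CREB and keeps it off DNA. Per the series design, every array held RNA pooled from 3 to 4 mice that shared age, sex and genotype, so each replicate was a pool. The 6 groups were VP16-CREB and control littermates at 3 weeks off dox (3 pools each, mice of 6 weeks), VP16-CREB and control littermates at 1 week off dox (2 pools each, mice of 3 weeks), and A-CREB and control littermates of 6 weeks (3 pools each). The early A-CREB arrays that the design text mentions were not analysed here.

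The deposited value of each probe set and array was an intensity on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, which give no version. The mean of each array after leaving out 2% of the values at each end was 500 on all 16 arrays, so the authors had scaled the arrays to a common trimmed mean, and no further normalization between arrays was seen. MAS5 subtracts a mismatch signal for each probe pair, which makes low intensities noisy. No array file or detection call was used here. For arrays, their number limits the precision, and no counting depth applies.

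The 64 Affymetrix control probe sets were left out. Values were taken as log2 of the intensity plus a pseudocount of 10, where the median of all values was 99.1. Probe sets above that median on at least 2 arrays were kept, which left 27044 (60.0%), of which 23141 carried exactly 1 gene symbol (12732 genes) and 3903 did not. Of all probe sets, 34945 had 1 symbol, 932 several and 9160 none. Positions are those of the gene in the GRCm38 annotation. Statistics were computed in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and the figures with Python 3.11.15 and matplotlib 3.10.9.

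All 16 arrays entered 1 linear model with a coefficient per group, fitted with lmFit and tested with eBayes (two-sided moderated test), with 10 residual degrees of freedom and 3.44 prior degrees of freedom. Benjamini-Hochberg adjustment covered the 27044 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Each transgenic group was compared with its own littermates. The difference between the effects at 3 weeks and 1 week of VP16-CREB, and between the effects of VP16-CREB at 3 weeks and A-CREB, was tested as a contrast of the 2 differences, and the control groups were compared with each other. Overlaps of calls were tested with a one-sided Fisher exact test. Values are given as the mean intensity ± SD over pools, and folds are of the intensity plus the pseudocount with the SE of the log2 difference.

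The 30 gene lists were tested with limma camera at a preset correlation of 0.01, on the probe set of highest mean per gene, with Benjamini-Hochberg adjustment over the 30 lists of a comparison, and again with an estimated correlation. The counts of members called rest on the probe set of highest mean per gene, adjusted over all probe sets and over the list alone. A gene called only at another of its probe sets is not counted. Some genes stand on more than 1 list. The named genes are, per transgene comparison, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and no overlap between the pools of both groups, up to 4 called members of each list (or the 2 of highest mean where no member was called), and Creb1 and Crem. For the other comparisons the 5 largest in each direction were taken. Unnamed transcripts are counted among them without being named. The comparisons, lists, naming rule, thresholds and alternative settings were fixed before the data were examined.

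The alternative settings were no pseudocount (values below 1 set to 1) and a pseudocount of 25, no filter and a filter on the mean, quantile normalization, arrays centred on their median, only the arrays compared in the fit, a trend with robust variances, 1 probe set per gene, array weights, a replicate block and each array left out in turn, so that at 1 week a lone pool was assumed to vary like the other groups, with fry and the estimated correlation for the lists and thresholds of 0.01 and 0.1 for the overlaps. The method was tested on simulated data with the design of these arrays and the residual SD of each probe set. The noise was drawn independently for each probe set. Of 50 probe sets changed 4-fold per comparison, 41 (82.0%) were called in the VP16-CREB design at 3 weeks, 36 (72.0%) at 1 week and 43 (86.0%) in the A-CREB design. Of 50 changed 2-fold, 23, 16 and 20 were called, with 8, 2 and 5 false calls over all simulated folds. Changes planted together ease the adjusted threshold, so smaller shares may be called where few probe sets change. All 10 simulated lists of 15 genes shifted by 0.5 log2 were called in each design. The simulation held no correlation between genes, so it did not test whether the list p-values hold for genes that vary together.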

Results

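The data comprised 16 arrays of mouse hippocampus, 1 RNA pool each. There were 3 of VP16-CREB mice and 3 of control littermates at 3 weeks off dox, 2 and 2 at 1 week off dox, and 3 of A-CREB mice and 3 of control littermates at 6 weeks of age. The median intensity was 118.9 to 129.3 on the 6 arrays of the 3 week VP16-CREB cohort and 75.0 to 93.2 on the other 10, although the trimmed mean was 500 on all. Pearson correlations across probe sets were 0.954 to 0.985 within groups (14 pairs of arrays) and 0.885 to 0.933 between that cohort and the others (60 pairs), and the main axis of a principal component analysis, with 52.96% of the variance, set the cohort apart. Each transgenic group has control littermates in its own cohort, so the transgene comparisons stay within cohorts. The intensity ratio of the 3' and 5' actin probe sets, a measure of RNA integrity, was 1.36 to 1.61 in the 3 week cohort and 1.37 to 2.48 in the others. By Xist (34.5 and 63.4) and Y-linked transcripts, replicate 1 of both groups in the A-CREB cohort came from males. Replicate 2 of the A-CREB controls had a weaker Y-linked signal beside a high Xist intensity (3611), and the VP16-CREB cohorts were female. The 18S rRNA signal was highest in replicate 3 of the A-CREB controls (1735) and of the A-CREB pools (3288).

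The comparison at 3 weeks off dox asks what prolonged CREB activity changes in the hippocampus. Genes of microglia, reactive astrocytes, antigen presentation and the interferon response rose in the VP16-CREB pools, together with CREB target genes, and markers of dentate granule neurons fell. The largest rise was that of Cst7 (chromosome 2, 150570415 to 150578944), which encodes cystatin F, a protease inhibitor of immune cells. Its intensity was 2963 ± 749 (SD, n = 3) against 12.6 ± 9.34 (n = 3) in controls, a 136-fold rise (log2 7.08, SE 0.55, adjusted p = 5.05e-06). Dgkk, a diacylglycerol kinase gene on chromosome X, rose 26.7-fold (1508 ± 399 against 46.3 ± 11.8, adjusted p = 2.35e-07). Pdyn, the prodynorphin gene on chromosome 2 and a known CREB target, rose by 3.03 log2 (1156 against 134 in controls, SE 0.19, adjusted p = 1.43e-06).

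The other large rises were mostly of immune genes. The chemokine gene Ccl3 rose 46.7-fold, the pattern receptor gene Clec7a 39.0-fold, the MHC class II gene H2-Ab1 38.3-fold and Glycam1, which encodes a mucin-like ligand of L-selectin, 31.2-fold, with adjusted p of 4.81e-05, 1.15e-05, 2.15e-06 and 0.000416. Cd52, a leukocyte surface glycoprotein, rose 19.4-fold, the lysozyme gene Lyz1 17.4-fold and Itgax, the integrin CD11c, 16.9-fold, with adjusted p of 1.47e-06, 0.000174 and 0.000568. The controls of Ccl3 (2.99 ± 0.82) and Glycam1 (5.46 ± 5.08) lay below the pseudocount of 10, so their folds depend on it: without a pseudocount the log2 differences were 7.68 for Ccl3, 6.78 for Glycam1 and 8.09 for Cst7. Of the 5 Creb1 probe sets that passed the filter (chromosome 1, 64532794 to 64604548; another did not pass), the most changed rose 19.1-fold (1167 ± 87.7 against 53.6 ± 18.7, adjusted p = 6.1e-05) and another 4.82-fold (487 ± 126 against 90.8 ± 5.09, adjusted p = 0.00201). The other 3 Creb1 probe sets differed by 0.14, -0.22 and -0.12 log2 and were not called. Whether the 2 raised probe sets read the VP16-CREB transgene was not examined, so they do not show a rise of the endogenous gene. Crem, a CREB target that encodes a related factor, rose 2.08-fold at 1 probe set (796 ± 122 against 376 ± 49.2, adjusted p = 0.014), while the other that passed the filter differed by 0.71 log2 (adjusted p = 0.266).

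The largest fall was that of Dsp, the desmoplakin gene (188 ± 53.7 against 827 ± 101, log2 -2.11, SE 0.29, adjusted p = 0.000581). Next came Rasl10a, a Ras-like GTPase gene (271 ± 45.2 against 1151 ± 7.07, log2 -2.06, SE 0.20, adjusted p = 2.85e-05). Lrrtm4, which encodes a synaptic adhesion protein, had a log2 difference of -1.83 and C1ql2, a gene of a secreted synaptic C1q-like protein, -1.78, with adjusted p of 4e-04 and 0.00397. Lct, the lactase gene, followed at -1.56 and Stxbp6, a gene of a SNARE-binding protein, at -1.54, with adjusted p of 7.54e-05 and 0.000326. The falls of Traip (-1.71), Nucks1 (-1.70), Plk5 (-1.61) and the splicing factor gene Sf1 (-1.49) were close to the threshold, with adjusted p of 0.0259, 0.0497, 0.0421 and 0.0462.

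Of 19 measured microglia and macrophage markers, 18 rose (18 adjusted over the list alone), and the median log2 difference of the list was 2.08 (camera adjusted p = 2.58e-32). Trem2, a microglial receptor gene, rose by 2.84 log2, Ly86 by 2.83, the lysosomal gene Cd68 by 2.73 and Tyrobp, the signalling partner of TREM2, by 2.68. Reactive astrocyte genes had a median of 2.41 (adjusted p = 2.78e-22), and 13 of 17 rose (14 adjusted over the list alone). Among them were the chemokine gene Cxcl10 by 3.65, the lipocalin gene Lcn2 by 3.33, Serpina3n by 2.96 and Timp1, a metalloproteinase inhibitor gene, by 2.87. Of 8 complement genes 5 rose (6 adjusted over the list alone, median 1.97, adjusted p = 3.04e-11), led by C1qc (2.63), C1qa (2.50), C1qb (2.28) and the receptor gene C3ar1 (2.17). C1qa, C1qb and C1qc also stand on the microglia and macrophage list, so the 2 rises are not separate. Of 23 interferon response genes 18 rose (22 adjusted over the list alone, median 1.49, adjusted p = 6.26e-27). Among them were Oasl2 by 2.72, Irf7 by 2.19 and Ifit1 by 2.15. Of 12 genes of MHC class I and antigen presentation 9 rose (11 adjusted over the list alone, median 1.38, adjusted p = 2.2e-15). H2-K1 was at 2.52, H2-D1 at 2.17, the proteasome subunit gene Psmb8 at 2.00 and the peptide transporter gene Tap1 at 1.59. General astrocyte markers had a median of 0.55 (adjusted p = 0.000129), and 2 of 13 rose (7 adjusted over the list alone), the water channel gene Aqp4 by 1.13 and Mlc1 by 0.93. Outside that count, 1 of 2 measured Sox9 probe sets was called higher. These 6 lists were also called with an estimated correlation, with adjusted p from 0.00338 to 0.0292.

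Of 26 CRE-driven CREB target genes 11 rose and none fell (13 and 1 adjusted over the list alone), with a median of 0.68 (adjusted p = 1.54e-08, and adjusted p = 0.0257 with an estimated correlation). After Pdyn, the largest were Nfil3 (2.02), the activin subunit gene Inhba (1.78) and Fosb (1.53). Of 25 activity-dependent immediate early genes 4 rose (6 adjusted over the list alone), Atf3 by 3.92, Fosb by 1.53, Fos by 1.46 and Trib1 by 0.75, and the list itself was not called (median 0.14, adjusted p = 0.137). Without control replicate 1 or transgenic replicate 2 that list was called (medians of 0.225 and 0.192, camera adjusted p of 0.0399 and 0.0468). In the list of the CREB and CREM family and cofactors, 1 of 11 rose (Crem) and 1 fell (Crtc1, a CREB coactivator gene, -0.70), the same counts adjusted over the list alone (median -0.08, adjusted p = 0.317). The 2 raised Creb1 probe sets are not the one counted there. Of 21 apoptosis and p53 response genes 6 rose (8 higher and 1 lower adjusted over the list alone, median 0.49, adjusted p = 8.99e-06, and adjusted p = 0.00398 with an estimated correlation). Their largest rises were those of the BH3-only gene Pmaip1 at 2.78, the cell cycle inhibitor gene Cdkn1a at 2.43, Casp8 at 1.00 and Gadd45g at 0.82. Of 15 neurotrophic and growth factor genes 4 rose (5 higher and 2 lower adjusted over the list alone, median 0.26, adjusted p = 0.0432, and adjusted p = 0.102 with an estimated correlation). They were Inhba, Tgfb1 by 1.75, Igfbp2 by 1.63 and Bdnf by 1.11. Outside that count, 1 of 4 measured Igf1 and 1 of 7 Ntrk2 probe sets were called higher and 1 of 6 Igfbp4 probe sets lower. Of 19 neuropeptide and granin genes 5 rose (5 adjusted over the list alone, median 0.37, adjusted p = 0.00215, and adjusted p = 0.0292 with an estimated correlation). They include Pdyn, the galanin gene Gal by 1.27, the neuropeptide Y gene Npy by 1.00 and Chga by 0.92. The neurotrophic list lost its call without control replicate 1 or 2 or transgenic replicate 1 or 3 (adjusted p of 0.0574, 0.0592, 0.0522 and 0.0812).

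Of 12 dentate granule cell markers 10 fell (10 adjusted over the list alone), with a median of -1.34 (adjusted p = 4.83e-15, and adjusted p = 0.00338 with an estimated correlation). Among them were C1ql2, Dsp, Plk5 and Lct. The 8 CA1 pyramidal neuron markers had a median of -0.59 (adjusted p = 4.41e-06, and adjusted p = 0.00496 with an estimated correlation). None was called among all probe sets and 6 were lower adjusted over the list alone, with Ccn3 at -0.62 and Wfs1 at -0.67. Of 9 CA3 markers 1 fell (Nptx1, -0.74, 1 adjusted over the list alone), and the list was not called (median -0.10, adjusted p = 0.293). Of 15 interneuron markers 2 rose (2 adjusted over the list alone), the vesicular GABA transporter gene Slc32a1 by 1.23 and Npy (median 0.24, adjusted p = 0.019, and adjusted p = 0.102 with an estimated correlation). Of 39 voltage-gated and potassium channel genes 4 fell (6 adjusted over the list alone), Kcnd2 (-0.83), Kcnab1 (-0.80), Kcnip4 (-0.75) and Kcnip2 (-0.74), with a list median of -0.31 (adjusted p = 1.01e-08, and adjusted p = 0.0292 with an estimated correlation). Of 9 GABA-A receptor subunit genes 1 fell, Gabrd at -0.89 (3 lower adjusted over the list alone, median -0.19, adjusted p = 0.0042, and adjusted p = 0.11 with an estimated correlation). Glutamate receptor and postsynaptic genes had no member called and 5 of 24 lower adjusted over the list alone, with Gria2 at -0.43 and Gria1 at -0.47 (median -0.37, adjusted p = 0.00016, and adjusted p = 0.0685 with an estimated correlation). Outside that count, 1 of 3 measured Homer2 probe sets was called lower. Presynaptic vesicle genes had no member called in either way, with Snap25 at -0.19 and Syt1 at -0.32 (21 measured, median -0.18, adjusted p = 0.0215, and adjusted p = 0.387 with an estimated correlation). The presynaptic list lost its call without control replicate 2 or transgenic replicate 2 (medians of -0.048 and -0.062, adjusted p of 0.159 and 0.0929). The interneuron list lost its call without control replicate 3 (median 0.152, adjusted p = 0.0518).

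None of 11 oligodendrocyte and myelin markers was called (median 0.02, adjusted p = 0.871), with the myelin genes Mbp at -0.11 and Cnp at -0.18. No member of 4 further lists was called, nor any adjusted over the list alone. These were 7 oligodendrocyte precursor markers (median 0.25, adjusted p = 0.153, Olig1 at 0.29, Pdgfra at -0.04) and 12 endothelial and pericyte markers (median 0.15, adjusted p = 0.293, Rgs5 at 0.07, Slc2a1 at 0.30). The other 2 were 3 blood cell genes (median 0.25, adjusted p = 0.744, Hbb-b2 at 0.25, Alas2 at -0.19) and 4 sex-linked genes (median -0.24, adjusted p = 0.581, Xist at -0.27, Uty at -0.47). The 7 thalamus and striatum markers, a check of the dissection, were not called (adjusted p = 0.871, Pde10a at -0.24, Prkcd at 0.27), with a median of 0.12 but a mean of -0.01. The 9 choroid plexus markers had a median of -0.66 with no member called in either way (adjusted p = 0.0152, and adjusted p = 0.387 with an estimated correlation), with Ttr, the transthyretin gene of that tissue, at -0.80 and Kcnj13 at -0.66. Another Ttr probe set ranged from 2671 to 29500 over the 6 arrays of the cohort. Of 19 immature neuron and proliferation genes 1 rose, Cdk1 by 0.97 (2 adjusted over the list alone, median 0.08, adjusted p = 0.361). Of 20 heat shock and unfolded protein response genes 2 rose, Hspb8 by 0.78 and Ddit3 by 0.60 (2 adjusted over the list alone, median 0.20, adjusted p = 0.0232, and adjusted p = 0.276 with an estimated correlation). Outside that count, 2 of 3 measured Hspa1b probe sets were called higher. The 14 circadian clock genes had no member called in either way, with Nr1d2 at -0.18 and Tef at -0.36 (median -0.24, adjusted p = 0.0232, and adjusted p = 0.276 with an estimated correlation). Leaving out 1 array ended the call of the choroid plexus list (without control replicates 2 and 3 and transgenic replicate 1, adjusted p of 0.0592, 0.0655 and 0.205). Its medians in these fits were -0.534, -0.359 and -0.239. The calls of 2 more lists also ended, with adjusted p of 0.0654 and 0.0836 for heat shock (control 1 and transgenic 3) and 0.0736 and 0.0798 for the clock (control 2 and transgenic 3).

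**Figure D1:**
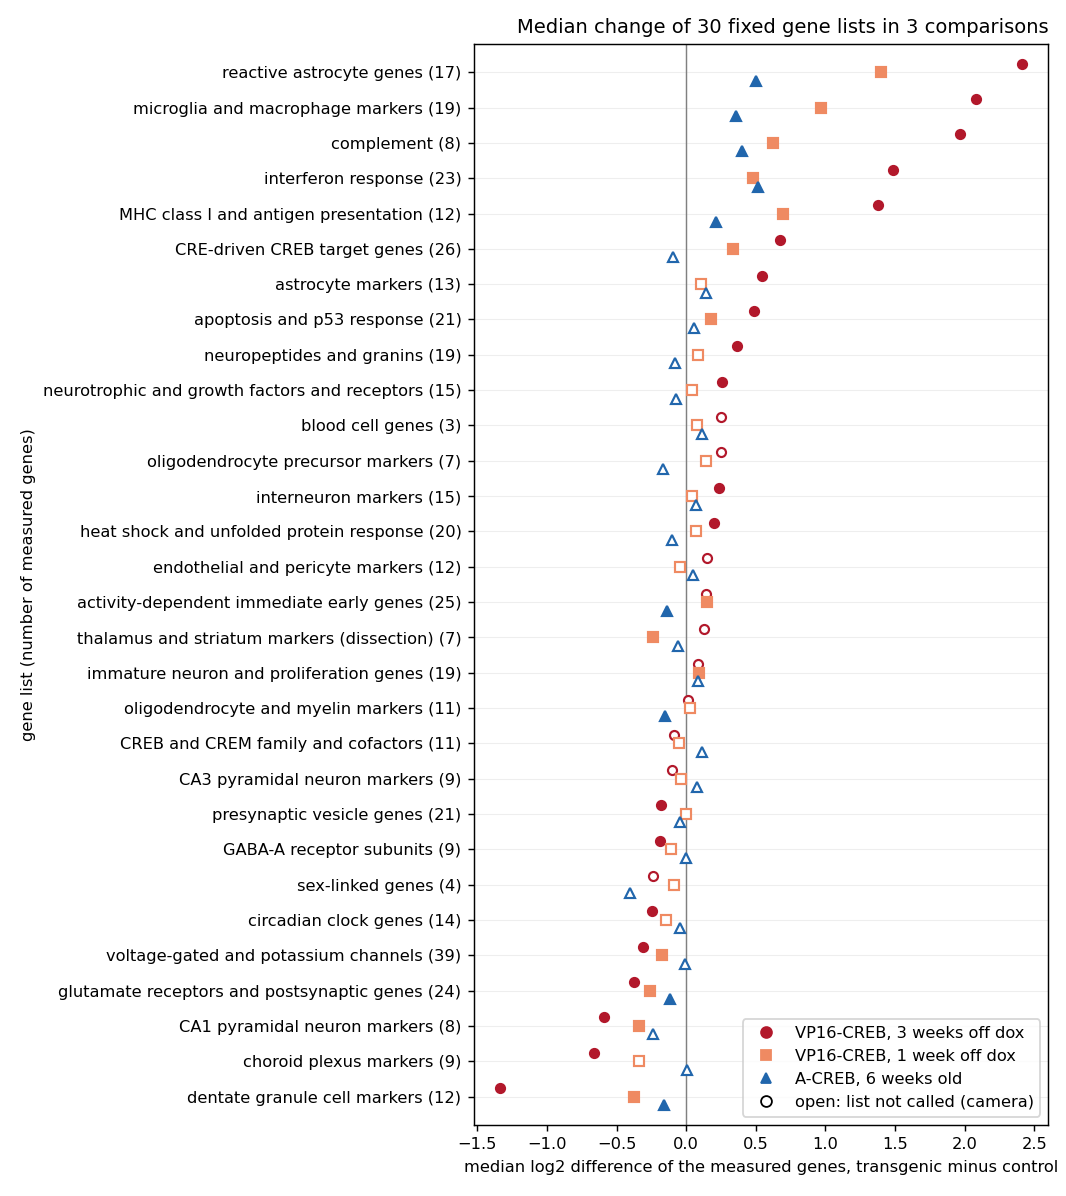
Median log2 difference from control littermates (x axis) of 30 gene lists (y axis, with the number of measured genes) in VP16-CREB at 3 weeks (circles) and 1 week (squares) off dox and in A-CREB (triangles). Filled symbols were called by camera with the preset correlation; reactive astrocyte genes lay at 2.41, 1.40 and 0.50, and dentate granule cell markers at -1.34, -0.37 and -0.16.

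In all, 1062 of 27044 probe sets were called at 3 weeks off dox, 886 higher (658 genes) and 176 lower (137 genes), and 599 and 48 of them changed at least 2-fold. Of the 30 lists, 12 were higher and 8 lower (9 and 3 with an estimated correlation). Leaving out 1 array at a time gave 584 to 854 calls, among them 675 without control replicate 1, 706 without control replicate 3, 675 without transgenic replicate 2 and 584 without transgenic replicate 3, and array weights raised the count to 4137. Calls near the threshold were the least stable: Gal and Bdnf each lost theirs in 12 of 18 and 19 alternative settings (single arrays left out included), Plk5, Nucks1, Gadd45g, Trib1 and Ddit3 in 11, and Traip, Kcnd2, Kcnab1, Kcnip4, Nptx1 and Crtc1 in 10.

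**Figure D2:**
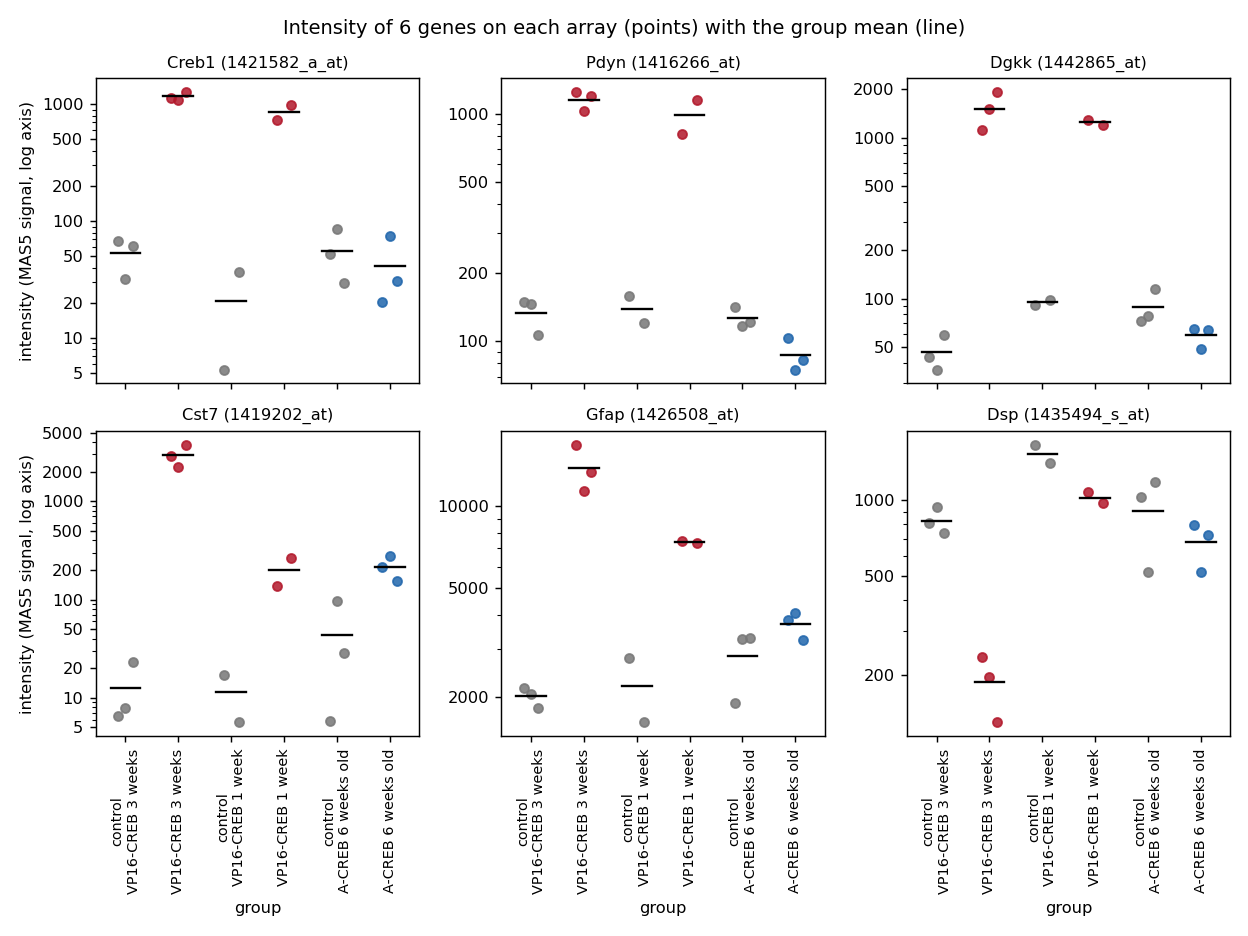
Intensity (y axes, log scale) of the probe sets of Creb1, Pdyn, Dgkk, Cst7, Gfap and Dsp on each of 16 arrays, by group (x axes); points are pools, colours mark control, VP16-CREB and A-CREB groups, and lines are group means. Creb1 lay at 735 to 1266 in the 5 VP16-CREB pools and at 5.38 to 85.1 in the other pools.

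The comparison at 1 week off dox, with 2 pools per group of mice of 3 weeks, asks which changes come early. The same Creb1 probe set rose 32.3-fold (863 ± 181 against 20.9 ± 21.9, SD, n = 2 each, adjusted p = 0.00143), with the other raised Creb1 probe set at 2.81 log2 (adjusted p = 0.0178). Pdyn rose 6.62-fold (986 ± 237 against 139 ± 26.5, SE 0.23 log2, adjusted p = 0.000138). The other 3 Creb1 probe sets differed by -0.19, -0.16 and 0.19 log2, and Crem by 0.80 and 0.82 (adjusted p of 0.579 and 0.843). As at 3 weeks, the raised Creb1 probe sets were not examined for whether they read the transgene. The log2 difference of the more changed one, 5.01, was 4.22 without control replicate 1 and 5.81 without control replicate 2, and that of the other ran from 2.12 to 3.50 over the alternative settings, with its call lost in 6 of 14. Dgkk rose 11.99-fold (1245 ± 68.4 against 94.6 ± 4.16, adjusted p = 0.000116), and Timp1 11.97-fold (27.4 ± 29.6 in controls, adjusted p = 0.014). The log2 difference of Timp1 ran from 2.67 to 4.49 over the alternative settings, and its call was lost in 6 of 14, among them without control replicate 2 and without transgenic replicates 1 and 2 (adjusted p of 0.0921, 0.0866 and 0.0996). The call of Clec7a was lost without any 1 of the 4 arrays (0.0889 to 0.171). Immune genes among the largest rises were H2-Ab1 (11.2-fold, adjusted p = 0.00143), Clec7a (10.7-fold, 0.0195) and Cd52 (5.21-fold, 0.00807), where each second figure is the adjusted p. H2-Q5, an MHC class I locus annotated as a transcribed pseudogene, rose 9.62-fold (adjusted p = 0.000138). Pax1 (7.55-fold) and Sipa1l1 (5.18-fold) rose from control intensities of 5.50 and 4.50. These and the control intensity of H2-Q5 (6.42) lie below the pseudocount, so the folds depend on it, and the log2 difference of H2-Q5 ran from 2.46 to 4.53 over the alternative settings. The falls were those of Odf2 (-1.73), Dlk1 (-1.64), Ube2k (-1.35) and Mtf1 (-1.35), with adjusted p of 0.0105, 0.0498, 0.0364 and 0.0498, and Odf2 (33.3) and Ube2k (33.3) were dim in the controls too.

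Microglia and macrophage markers had a median of 0.97 at 1 week (adjusted p = 4.9e-29): 3 of 19 rose (15 adjusted over the list alone), Ly86 by 1.92, Cd68 by 1.84 and the leukocyte gene Ptprc by 1.21. Reactive astrocyte genes had a median of 1.40 (adjusted p = 1.38e-23), and 5 of 17 rose (12 adjusted over the list alone). Among them were Gfap, the astrocyte filament gene, by 1.80 (7378 against 2188), the receptor genes S1pr3 by 1.57 and Osmr by 1.505, and Timp1. Outside that count, 1 of 3 measured Vim probe sets was called higher. Of 12 genes of MHC class I and antigen presentation 2 rose (4 adjusted over the list alone, median 0.69, adjusted p = 6.93e-10), H2-K1 by 1.45 and Psmb9 by 1.01. Of 23 interferon response genes 1 rose, Gbp2 by 1.69 (2 adjusted over the list alone, median 0.48, adjusted p = 1.79e-11). Complement genes had a median of 0.62 (adjusted p = 0.000117), with none of 8 called and 4 higher adjusted over the list alone, C1qa being at 0.95. Apoptosis and p53 response genes had a median of 0.18 (adjusted p = 0.00434), with Pmaip1 up by 2.16 and 3 higher adjusted over the list alone. With an estimated correlation these 6 lists stayed called, with adjusted p from 0.00522 to 0.0482, and leaving out 1 array ended only the apoptosis call (without control replicate 1, adjusted p = 0.0517).

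CRE-driven CREB target genes had a median of 0.34 (adjusted p = 7.73e-06, and adjusted p = 0.07 with an estimated correlation), with only Pdyn called of 26 and 3 higher adjusted over the list alone. Immediate early genes had a median of 0.15 with no member called and 2 higher adjusted over the list alone (adjusted p = 0.000367, and adjusted p = 0.237 with an estimated correlation), with Egr1 at -0.05 and Homer1 at 0.07. In the list of immature neuron and proliferation genes, the DNA topoisomerase gene Top2a rose by 1.78 and the mitotic kinase gene Cdk1 by 1.52. The list had 3 members higher adjusted over the list alone (median 0.09, adjusted p = 0.00784, and adjusted p = 0.133 with an estimated correlation). Dentate granule cell markers had a median of -0.37 with none of 12 called and 2 lower adjusted over the list alone, Stxbp6 being at -0.67 (adjusted p = 3.78e-05, and adjusted p = 0.0482 with an estimated correlation). CA1 markers had a median of -0.34, with Ccn3 at -0.45 (adjusted p = 0.00144, and adjusted p = 0.0482 with an estimated correlation). Glutamate receptor and postsynaptic genes (-0.26, adjusted p = 0.00206), voltage-gated and potassium channel genes (-0.18, adjusted p = 0.00551) and thalamus and striatum markers (-0.24, adjusted p = 0.0408) were lower as lists without any called member. With an estimated correlation they had adjusted p = 0.142, adjusted p = 0.289 and adjusted p = 0.133. Leaving out 1 array ended several of these calls. Of the lists that lost their call without control replicate 1, the median was 0.09 for CREB targets and 0.01 for immediate early genes. It was 0.17 for immature neuron genes and -0.27 for thalamus markers. Without control replicate 2 the medians were -0.19 for CA1 markers, -0.14 for glutamate receptor genes, 0.16 for immature neuron genes and -0.46 for thalamus markers. The channel median turned to 0.02 there. Without transgenic replicate 1 the median was -0.14 for channels and -0.20 for thalamus markers. Without transgenic replicate 2 it was 0.03 for immediate early genes and 0.12 for immature neuron genes. The other 16 lists were not called.

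In all, 64 probe sets were called at 1 week, 59 higher and 5 lower (46 and 4 genes), and 1424 had an unadjusted p under 0.05, where chance would give 1352. With arrays centred on their median, which moved the median of all log2 differences from 0.02 to -0.09, 50 were higher and 12 lower, and the median of the immature neuron and proliferation genes would then lie below 0. The calls rest on the spread shared by all 16 arrays: none remained when the 4 arrays were fitted alone (1284 at an unadjusted p under 0.05). Over the 27 named probe sets called, 36 of 108 fits without 1 array kept the call. Psmb9 lost its call in 12 of 15 alternative settings, Cdk1 in 11 of 15, and Pax1, Sipa1l1, Dlk1, Ube2k and Mtf1 in 10 of 13 to 15. Leaving out 1 array gave 16 to 45 calls, the lowest without transgenic replicate 1 (38 without control replicate 2 and 39 without transgenic replicate 2).

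The comparisons at 1 week and 3 weeks shared 51 probe sets called higher in both, where 1.93 would be expected from independent lists (one-sided Fisher exact p = 8.05e-68). The test takes probe sets as independent, which they are not, so this p does not measure replication over pools. The shared probe sets include those of Creb1, Pdyn, Dgkk and Clec7a. None was called lower in both (0.0325 expected). The overlap was 31, 18, 12 and 16 without control replicates 1 and 2 and transgenic replicates 1 and 2 at 1 week. Of the 1062 probe sets called at 3 weeks, 975 (91.8%) had the same sign at 1 week (59.8% over all 27044 probe sets), with a median difference of 0.52 log2 at 1 week against 1.26 at 3 weeks for those called higher, and -0.30 against -0.84 for those called lower. These probe sets were chosen at 3 weeks, which favours larger differences there, so the medians do not show a growth of the effect. Across all probe sets, which are not independent replicates, the log2 differences had a Spearman correlation of 0.271, which was 0.0964 without control replicate 2 of the 1 week cohort and 0.150 without a filter. The effect at 3 weeks minus the effect at 1 week was larger for microglia and macrophage markers (median 0.95, adjusted p = 1.39e-19), interferon response genes (0.92, 1.39e-19) and complement genes (1.40, 3.29e-12), where each second figure is the camera adjusted p. It was also larger for genes of MHC class I and antigen presentation (0.88, 8.15e-09), reactive astrocyte genes (0.87, 2.72e-09) and apoptosis and p53 response genes (0.27, 0.00303). The same difference was negative for dentate granule cell markers (median -0.77, adjusted p = 9.46e-11). With an estimated correlation these 7 of the 15 lists called stayed called (6 higher and 1 lower). Per probe set, limma called 1 difference between the 2 effects, of an unnamed transcript, with 1349 at an unadjusted p under 0.05, where chance would give 1352. The 2 cohorts differ in age, time off dox and array cohort, so the difference between the effects cannot be assigned to the time off dox alone.

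**Figure D3:**
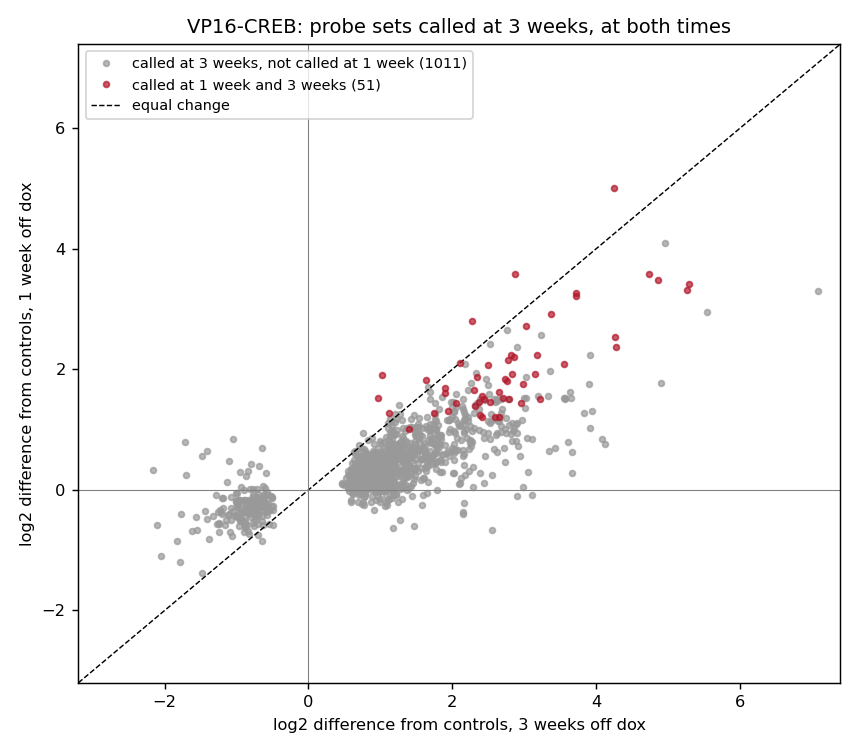
Log2 difference of VP16-CREB from control littermates at 3 weeks (x axis) and 1 week (y axis) off dox for the 1062 probe sets called at 3 weeks; darker red points are the 51 called at both times, grey points those not called at 1 week, and the dashed line marks equal change. Of the 1062, 975 had the same sign at both times, and most lie closer to 0 on the y axis than on the x axis. The points were chosen by their call at 3 weeks, which favours larger values on the x axis.

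The A-CREB comparison asks what chronic inhibition of CREB changes in mice of 6 weeks. The genotype labels name an F1 background for the A-CREB pools only, so a difference in genetic background was not separated from the transgene here. No probe set was called by limma: 1171 had an unadjusted p under 0.05, where chance would give 1352, the smallest adjusted p was 0.0801, and other limma settings gave 0 to 7 calls. Interferon response genes were higher as a list (median 0.52, adjusted p = 9.29e-22, and adjusted p = 0.0486 with an estimated correlation), with 14 of 23 higher adjusted over the list alone and all 23 with a positive difference. Its most abundant members were Ifi27 (0.13) and Ifitm3 (0.52). Reactive astrocyte genes (median 0.50, adjusted p = 8.4e-10), complement genes (0.40, adjusted p = 6.85e-05), microglia and macrophage markers (0.36, adjusted p = 3.56e-08) and genes of MHC class I and antigen presentation (0.22, adjusted p = 0.0104) were also higher. With an estimated correlation they were not called (adjusted p = 0.0624, adjusted p = 0.0956, adjusted p = 0.308 and adjusted p = 0.381). Adjusted over the list alone, 2 reactive astrocyte genes and 2 microglia markers were higher and no gene of the other 2 lists. The levels of abundant members were 3695 against 2811 for Gfap (log2 0.43), 2688 against 1902 for Vim (0.56), 2135 against 1636 for C1qa (0.37), 4623 against 3029 for Ctss (0.63) and 5176 against 4208 for B2m (0.31). The MHC class I list lost its call without control replicate 1 or A-CREB replicate 2 (adjusted p of 0.306 and 0.325).

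CRE-driven CREB target genes were not called as a list in A-CREB (median -0.10, adjusted p = 0.202), with none of 26 called in either way and Sst at -0.08 and Scg2 at -0.17. Pdyn, among those not called, lay at 75.2 to 103 in the A-CREB pools and at 117 to 141 in their controls. Immediate early genes were lower (median -0.13, adjusted p = 0.00223, and adjusted p = 0.381 with an estimated correlation), with Egr1 at -0.09 and Egr3 at 0.03. Dentate granule cell markers were lower (median -0.16, adjusted p = 0.00223, and adjusted p = 0.24 with an estimated correlation), with 2 of 12 lower adjusted over the list alone, Calb1 at 0.09 and Stxbp6 at -0.43. Oligodendrocyte and myelin markers (median -0.15, adjusted p = 0.0318, Mbp at -0.06) and glutamate receptor and postsynaptic genes (median -0.12, adjusted p = 0.0483, Camk2a at -0.11) were lower. No member was called in either way, and with an estimated correlation each had adjusted p = 0.381. Without control replicate 1 the adjusted p was 0.13 for dentate markers and 0.231 for glutamate receptor genes, without control replicate 2 it was 0.433 for oligodendrocyte markers, and without control replicate 3 it was 0.098 for immediate early genes and 0.232 for glutamate receptor genes. Without A-CREB replicate 1 it was 0.371 for oligodendrocyte markers and 0.376 for glutamate receptor genes, and without A-CREB replicate 2 it was 0.298 for immediate early genes, 0.126 for oligodendrocyte markers and glutamate receptor genes and 0.0997 for dentate markers. The other 20 lists were not called. The Creb1 probe set most raised in VP16-CREB mice was at 41.7 ± 28.7 against 55.8 ± 27.9 in A-CREB, and the other 4 Creb1 probe sets differed by -0.01, 0.23, 0.81 and 0.22 log2, with adjusted p of 1. Crem differed by 0.12 and 0.07. Without the 2 male pools, an alternative chosen after seeing the data, 4 lists were called, with the interferon list at a median of 0.43 (adjusted p = 2.31e-10). The self-test called 43 of 50 simulated 4-fold changes in this design and 20 of 50 2-fold changes. Its planted changes eased the adjusted threshold and its noise was independent, so these shares may be too high for this comparison. Neither Trat1 probe set, at 3.36 and 3.21 log2, was called (limma adjusted p = 0.105 and 0.0801).

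VP16-CREB at 3 weeks and A-CREB were compared at the same age, each against its own littermates. The 2 cohorts differ in line, dox history, array cohort and the sex of some pools. The labels also name an F1 background for the A-CREB pools only. So the difference between the effects cannot be assigned to the transgenes alone. The effects differed at 240 probe sets, 224 with a higher and 16 with a lower effect in VP16-CREB (2351 at an unadjusted p under 0.05). Of the 240, 232 were called with the same sign in VP16-CREB at 3 weeks. Leaving out 1 array gave 114 to 218 probe sets with differing effects. The count was 147 and 152 without VP16-CREB controls 1 and 3, 129 and 114 without VP16-CREB replicates 2 and 3, and 159 without A-CREB replicate 3. The largest differences in log2 were those of H2-Ab1 (5.78, where A-CREB was at -0.52), Dgkk (5.24, A-CREB at -0.50), Creb1 (4.65), Cst7 (4.63) and the stress response gene Atf3 (3.86), with adjusted p of 0.000129, 5.8e-06, 0.00299, 0.0108 and 0.0107. The Creb1 value is that of the probe set most raised in VP16-CREB, which was not examined for whether it reads the transgene. The effect was lower in VP16-CREB for Trat1, a T cell receptor adaptor gene (-3.80), Lrrtm4 (-1.69), Rasl10a (-1.54), the ephrin receptor gene Epha7 (-1.22) and the potassium channel gene Kcnu1 (-1.17), with adjusted p of 0.0316, 0.0335, 0.0189, 0.0247 and 0.0272. Trat1 was the only gene among these that moved mainly in A-CREB (3.36 log2 against -0.44 in VP16-CREB). Its call was lost in 12 of 21 alternative settings. Among them were each fit without 1 of the 6 arrays of the VP16-CREB cohort (adjusted p of 0.0663 to 0.0981) and those without A-CREB replicate 2 or 3 (0.0708 and 0.082). Lrrtm4 lost its call in 12 of 23 settings, Kcnu1 in 11, Epha7 in 10, Rasl10a in 6 and Cst7 in 1 of 22. Without transgenic replicate 3 of the VP16-CREB cohort, for example, the adjusted p was 0.0963 for Lrrtm4, 0.0925 for Kcnu1, 0.0764 for Epha7 and 0.0741 for Rasl10a. Among the 12 single arrays, only leaving out A-CREB control 1 or A-CREB replicate 2 kept the call of Lrrtm4, and the call of Rasl10a was lost without VP16-CREB controls 1 and 3, VP16-CREB replicates 2 and 3 and A-CREB control 2. That of Kcnu1 was kept without A-CREB control 2 or A-CREB replicates 1 and 3, and that of Epha7 without VP16-CREB control 2, A-CREB control 1 or A-CREB replicates 1 and 2.

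By list, the effect of VP16-CREB exceeded that of A-CREB for microglia and macrophage markers (median of the differences 1.86, adjusted p = 5.34e-28), reactive astrocyte genes (1.73, adjusted p = 4.82e-16), and complement genes (1.54, adjusted p = 1.5e-08). It also did for genes of MHC class I and antigen presentation (1.09, adjusted p = 3.13e-12), interferon response genes (0.79, adjusted p = 4.19e-12) and CRE-driven CREB target genes (0.68, adjusted p = 1.16e-09). It was more negative for dentate granule cell markers (-0.94, adjusted p = 1.21e-10) and CA1 markers (-0.30, adjusted p = 0.00258). These 8 stayed called with an estimated correlation, and of the 18 lists called 10 did. No probe set was called in both comparisons, since none was called in A-CREB. Among the 1062 probe sets called in VP16-CREB at 3 weeks, 781 (73.5%) had the same sign in A-CREB (52.4% over all 27044 probe sets), with a median A-CREB difference of 0.17 log2 for those called higher and -0.11 for those called lower. A split of the A-CREB cohort that follows the actin 3' to 5' ratio instead of genotype gave 77.9%, so this share cannot be assigned to the transgene. Across all probe sets the Spearman correlation of the effects was 0.0825, and it turned to -0.0084 without replicate 1 of the A-CREB controls and to -0.0026 without replicate 1 of the A-CREB pools.

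The control littermates show how far the cohorts differ without a transgene. Between the VP16-CREB controls of 6 weeks and of 3 weeks of age, 4866 probe sets were called, 3716 higher and 1150 lower at 6 weeks. The nuclear RNA Malat1 (chromosome 19, 5795690 to 5802672) was 88.2-fold higher (6976 ± 1253, n = 3, against 101 ± 111, n = 2), the noncoding RNA Snhg11 48.2-fold, and 1 probe set each of Fgf14 37.6-fold, Kcnq5 28.7-fold and Kcnma1 27.6-fold. The younger controls of these 3 lay at 7.08, 5.49 and 7.34, below the pseudocount, so their folds depend on it (log2 4.31 to 6.97, 3.92 to 6.31 and 3.92 to 6.07 over the alternative settings). The log2 difference of Malat1, 6.46, was 5.19 without replicate 1 and 7.74 without replicate 2 of the younger controls. The lower genes were led by the choroid plexus gene Otx2 (-3.82), Nudt21 (-3.81), Clic6 (-3.71), Steap1 (-3.19) and Kcne2 (-3.05), and 8 of 9 choroid plexus markers were called lower (median -2.59, adjusted p = 2.07e-06, and adjusted p = 0.847 with an estimated correlation). With quantile normalization 2597 were higher and 2124 lower, and with arrays centred on their median, which moved the median of all probe sets from 0.07 to -0.48, 2407 were higher and 10293 lower. Leaving out control replicate 1 of the 1 week cohort gave 2458 calls. It also ended the calls of Steap1 and Kcne2 (adjusted p of 0.069 and 0.136), and that of Kcne2 was lost without replicate 1 of the older or replicate 2 of the younger controls (0.0924 and 0.0852).

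Between the A-CREB and the VP16-CREB controls, both of 6 weeks, 4746 probe sets were called, 982 higher and 3764 lower in the A-CREB controls. The largest falls were those of Snhg11 (-4.88), Fgf14 (-4.85), Malat1 (-4.72, 278 ± 139 against 6976 ± 1253) and Kcnq5 (-4.34), beside an unnamed transcript. The largest rises were those of Nudt21 (3.67), the growth hormone gene Gh (3.47, 618 ± 834 against 20.01 ± 22.5), Otx2 (2.87), Clic6 (2.86) and Alas2 (2.60). Gh lost its call in 5 of 15 alternative settings, among them without VP16-CREB control 1 or 2 or A-CREB control 2 (adjusted p of 0.0786, 0.0871 and 0.0817), with log2 differences from 2.22 to 4.61. Choroid plexus markers were higher in the A-CREB controls (6 of 9 called, median 1.80, adjusted p = 1.45e-05), as were oligodendrocyte and myelin markers (5 of 11, 0.62, adjusted p = 1.45e-05). So were oligodendrocyte precursor markers (3 of 7, 0.32, adjusted p = 0.0409), heat shock and unfolded protein response genes (6 of 20, 0.41, adjusted p = 0.0111) and reactive astrocyte genes (3 of 17, 0.40, adjusted p = 0.0272). Channel genes (-0.18, adjusted p = 0.0409) and genes of MHC class I and antigen presentation (-0.33, adjusted p = 0.0409) were lower. None of these 7 lists was called with an estimated correlation (adjusted p = 0.216 for oligodendrocyte and myelin markers and adjusted p = 0.516 for the others). With quantile normalization 2177 were higher and 2773 lower, and with arrays centred on their median, which moved the median of all probe sets from -0.05 to 0.48, 11652 were higher and 2581 lower. Both control comparisons use the 3 control pools of the 3 week VP16-CREB cohort. Within a comparison, age, time off dox and array cohort are not separated between the controls of 6 and 3 weeks, nor line, dox history and array cohort between those of both lines. Between the A-CREB controls of 6 weeks and the VP16-CREB controls of 3 weeks, which differ in age and line, 0 probe sets were called. This argues against age or line alone as the whole source of the calls in both comparisons, unless their effects offset each other.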

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

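The tests of the microglial rise, and those of age and background for the array cohort, were chosen only after the result was seen; the tests of nuclear RNA, of Trat1 and of the splits were written before.

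Differences between groups in the effect of the transgene brought up the following results. Between VP16-CREB at 3 weeks and 1 week off dox, 1 probe set, of an unnamed transcript, differed by -2.05 log2 (SE 0.24, adjusted p = 0.0201; -0.21 at 3 weeks and 1.84 at 1 week). Between VP16-CREB at 3 weeks and A-CREB, 240 differed. H2-Ab1 differed by 5.78, Dgkk by 5.24, Creb1 by 4.65, Cst7 by 4.63 and Atf3 by 3.86 log2, all raised in VP16-CREB. The Creb1 value is that of its most raised probe set, and whether this reads the transgene was not examined. Trat1 differed by -3.80, Lrrtm4 by -1.69, Rasl10a by -1.54, Epha7 by -1.22 and Kcnu1 by -1.17.

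Microglia and macrophage markers were higher in VP16-CREB at 3 weeks by a median of 2.08 log2. A lower share of neurons raises the markers of every other cell type alike, but the oligodendrocyte markers had a median of 0.0156 (-0.04 to 0.11 over fits without 1 array), against a lowest median of 1.99 for the microglia markers over such fits and a fit after quantile normalization. The latter also argues against a single array or the scaling as the whole source. The 2 measured erythroid genes, Alas2 (28.5 against 41.3) and Hbb-b2 (105 against 87.7), had upper 95% limits of 1.11 and 0.68 log2, below the microglia median. That met the condition, also written after the result was seen, for arguing against blood left in the tissue. Blood still cannot be told apart, since only 2 such genes were measured and Alas2 was dim. The rule that at least 3 are needed was set after this was seen. More microglia, or a higher expression of these genes in each, are candidate explanations that these data do not separate.

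The control pools of the 3 week VP16-CREB cohort had 3005 probe sets higher than in both other control groups, by medians of 1.89 log2 against the 1 week controls and, with the sign turned, -1.89 for the A-CREB controls against them. If the 2 comparisons were independent, 517 would be expected in both, but they share the 3 control pools of the cohort. The covariance of their log2 differences was 0.598, against 0.0446 from those shared pools in simulated draws with no group difference. Of these, 50.9% had no single gene symbol, against 14.4% of all kept. Age as the whole source was argued against, since the set was in part chosen for a difference between controls of the same age, and this held in pools not used for the choice (median 1.70 between the VP16-CREB and A-CREB pools, both of 6 weeks). Age would also raise the set in the A-CREB pools of 6 weeks over the VP16-CREB pools of 3 weeks, but its median there was -0.11. Those pools differ in line and transgene too, so a smaller part from age stays open. A background that lifts all dim probe sets alike was argued against as the whole source. After quantile normalization, which gives all arrays the same distribution, the median stayed at 1.49. Over fits without 1 array, 76.1 to 80.3% of the median was kept, just above a bound set after the result was seen. A background that lifts only some probe sets would pass this test, so it stays open. Nuclear and unspliced RNA carried through to labelling may add to the set but cannot be told apart: the smaller median of 9 nuclear RNAs was 0.61. Against both control groups, Miat (2.12 and 2.50), Kcnq1ot1 (2.37 and 2.70) and Neat1 (1.36 and 2.17) were called higher. Mirg (1.21 and 1.76) was called against the A-CREB controls only. Snhg14 (0.90 and 0.61), Gas5 (-0.03 and 0.28), Pantr1 (-0.14 and -0.10), Tug1 (-0.47 and -0.31) and Rian (-0.83 and -0.30) were not called.

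Trat1 (chromosome 16, 48730774 to 48810547) was higher in A-CREB at both probe sets (3.36 log2, 343 ± 83.6 against 32.9 ± 28.2, n = 3 each, adjusted p = 0.105; and 3.21, 401 ± 155 against 42.6 ± 39.0, adjusted p = 0.0801), neither of which passed the threshold. T cells in the A-CREB hippocampi cannot be told apart, since only 2 of 16 other T cell markers passed the filter, Zap70 (260 against 270) and Cd8a (52.0 against 55.1), with a median of 0.0478. That median lies below the bound of 0.5 set beforehand and neither marker rose, but their upper 95% limits of 0.902 and 1.33 exceed the bound. The condition on these limits was not part of the rule written before. The 12 markers under the filter were near the floor, at most 67.0 on any array (Icos), and went both ways, as in Cd3g (4.91 in A-CREB against 13.8), Cd5 (12.1 against 36.6), Cd3e (25.3 against 18.6) and Ctla4 (19.6 against 9.96). A change of the whole chromosome region was argued against by its 8 nearest measured genes, whose largest difference was 0.67 (1700026J12Rik), although Ift57 (0.46) had an unadjusted p of 0.00385. The genotype labels of the A-CREB pools name an F1 background and those of their controls do not, so a difference in genetic background may remain and was not tested.

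The 10 splits of 6 arrays into 3 and 3 cannot give a share under 0.05 (never under 0.1). VP16-CREB at 3 weeks had 1062 calls and the highest other split 1 (1 of 10 splits gave as many). The control littermates of both lines had 4746 and 0 (1 of 10), and the lists called at 3 weeks were 20 and 16 (1 of 10). The lists called in A-CREB were 9 and 11 (2 of 10), and the share of the same sign in A-CREB was 73.5% and 77.9% (2 of 10). For the calls in A-CREB, all 10 splits gave as many as the real 0, and the highest gave 94. That split, which also gave the 11 lists and the 77.9%, parts the arrays exactly by the actin 3' to 5' ratio (1.37 to 1.52 against 1.65 to 2.48), which points to a structure of the samples. With that ratio as a covariate, chosen after seeing the data, limma called 0 and the interferon list had a median of 0.57 (adjusted p = 1.37e-23). For the effect of VP16-CREB minus that of A-CREB, 12 of 100 splits gave as many as the real 240 and the highest 1386, so chance was not excluded by this count. The 12, the real one included, are all the drawn splits that keep the VP16-CREB grouping, and the others gave at most 3. In these draws, regrouping the A-CREB arrays did not lower the count, so it does not show that the A-CREB grouping matters.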

How the results depend on the processing

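The settings that leave out 2 arrays, the sex and actin covariates, and the overlaps and effect correlations of separate fits or without 1 array were tests chosen after seeing the data. Of the alternatives for genes named as called, 801 of 916 kept direction and threshold in VP16-CREB at 3 weeks and 184 of 285 at 1 week (330 of 432 and 36 of 108 without 1 array), and none reversed. The 1062 calls at 3 weeks became 4137 with array weights, 511 with a replicate block, 573 without the 2 arrays that deviate together and 552 without the 2 of lowest choroid plexus signal, and 584 to 854 without 1 array. The lists called became 12 with an estimated correlation (16 to 20 without 1 array). At 1 week the 64 became 32 without a filter, 0 with only the arrays compared (1284 at an unadjusted p under 0.05), 31 with weights, 0 with the block and 16 to 45 without 1 array. The lists became 8 with an estimated correlation, 9 with fry and 10 to 13 without 1 array. In A-CREB the 0 calls became 3 without a pseudocount, 2 with a pseudocount of 25, 2 with 1 probe set per gene, 2 without the male pools, 7 without the 2 arrays of highest 18S rRNA and 0 to 4 without 1 array. The lists became 1 with an estimated correlation, 2 with fry, 4 without the male pools and 4 to 11 without 1 array. With sex as a covariate limma called 0 (smallest adjusted p 0.0918). For the effect at 3 weeks minus 1 week, the 1 call became 2 without a pseudocount, 21 with quantile normalization, 9 with only the arrays compared, 3 with weights, 0 with a pseudocount of 25, no filter, a filter on the mean, centring, 1 probe set per gene or the block, and 0 to 5 without 1 array. For VP16-CREB minus A-CREB, the 240 became 138 without a filter, 404 with weights, 120 with the block and 114 to 218 without 1 array. The controls at 6 against 3 weeks gave 2597 with a filter on the mean, 12700 with centring, 1084 with 1 probe set per gene and 2458 to 4231 without 1 array, and those of both lines 2303, 14233, 985 and 3537 to 4432. The overlap of 51 became 22 without a filter, 29 with weights, 15 and 79 at adjusted p of 0.01 and 0.1, 0 with separate fits and 12 to 51 without 1 array. That with A-CREB became 1 with 1 probe set per gene, 1 at 0.1 and 0 to 2 without 1 array. Reversed were the channel list at 1 week without control replicate 2 (0.021, adjusted p = 0.876; lowest -0.343 without control replicate 1), the choroid plexus list in A-CREB without the male pools (-0.658, adjusted p = 0.0411) and the Spearman correlation of A-CREB with VP16-CREB at 3 weeks (-0.0084 and -0.0026 without replicate 1 of the A-CREB controls or transgenics; up to 0.1903 without A-CREB replicate 3). Fewer probe sets or arrays were tested with 1 probe set per gene and where arrays were left out; for the other settings the cause was not tested. The labels do not say that replicate numbers pair the pools. Deviations of pools of the same number correlated at -0.228 to 0.218 in the VP16-CREB cohorts and at -0.052, 0.407 and 0.265 in the A-CREB cohort, where replicates 1 share sex and replicates 3 a high 18S rRNA signal, and those of different numbers at -0.366 to 0.338. Low signal over background limits the precision of folds such as that of Cst7 (log2 8.09 without a pseudocount and 6.31 with 25).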

Other observations

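The test of the male pools below was chosen only after the result was seen, as were the genes named here, taken for their small p in A-CREB or, for P2ry12, as the microglia marker that was not called at 3 weeks.

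Several immune genes of smallest p in A-CREB moved the same way as in VP16-CREB at 3 weeks, without passing the threshold in A-CREB. Oasl2, an interferon-induced gene, was at 346 ± 30.2 in A-CREB against 134 ± 12.9 (n = 3 each, log2 1.301, adjusted p = 0.0801) and at 2.72 in VP16-CREB. Mpeg1, a macrophage perforin-like gene, was at 1290 ± 178.0 against 606 ± 157 (1.10, adjusted p = 0.321) and at 2.99 in VP16-CREB. Clec7a was at 382 ± 98.3 against 71.5 ± 39.1 (2.35, adjusted p = 0.307) and at 5.29, and the chemokine gene Ccl6 at 119 ± 3.38 against 43.4 ± 13.4 (1.303, adjusted p = 0.307) and at 3.55. Of the 20 named probe sets of smallest p in A-CREB, 11 had the same sign in VP16-CREB at 3 weeks and 9 the opposite, among the latter both of Trat1 (-0.25 and -0.44), Sh3bp5 (-1.26 in A-CREB, 0.02 in VP16-CREB) and Man2a2 (1.24 and -0.08). P2ry12, a receptor gene of resting microglia, differed by 0.42 log2 at 3 weeks (adjusted p = 0.801), where Trem2 rose by 2.84.

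Without the 2 male pools of the A-CREB cohort, limma called 2 probe sets, both lower.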
